A study of Homo sapiens with 4 samples.

How the data were processed

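RNA was sequenced from TPC1 cells, a human papillary thyroid carcinoma line, carrying either the empty retroviral expression plasmid pMSCV or pMSCV with SphK1, the sphingosine kinase that phosphorylates sphingosine to sphingosine-1-phosphate. Per the labels' protocols, cells grew in medium with 10% fetal bovine serum, puromycin at 0.5 μg/mL was applied from 48 h after infection and kept for 10 days to obtain stable lines, RNA was taken with Trizol, and libraries were made with the NEBNext Ultra RNA kit, whose standard form does not mark the strand. There were 2 libraries per group. Groups and replicate numbers were taken from the sample titles. The description of SphK1 replicate 2 names Sphk2 in place of Sphk1, so the levels of both kinases were examined in each library before any other gene. Nothing in the labels says whether the 2 libraries of a group came from separate cultures, so all p-values measure only the spread between these libraries, which may be technical.

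The deposited table gives whole-number read counts for each of the 4 libraries and 60504 Ensembl gene identifiers, per the file headers. The submitters' processing notes name HTSeq 0.6.0, DESeq (no version) and the genome build hg19, without a role or an order, and the aligner is not given in the sources used here. The column abbreviations were matched to the titles by the cell line or gene they begin with and by the replicate number, and no column of per-sample values was left unmatched. The table's gene coordinates were identical to those of GENCODE 29 on GRCh38 for 54241 of the 56996 identifiers found there (95.2%), although the notes name hg19, and coordinates below are given as the table gives them, on GRCh38. Symbols came from a table of Ensembl identifiers and names, which held 56558 of the identifiers. The same deposited table holds the authors' normalized signal, a mean of scaled counts per group, the authors' fold change as the ratio of these means, and the authors' p-value and adjusted p-value per gene. These were used only to describe the authors' deposited table in the closing section. Every other value was computed from the deposited counts. No row lacked a gene identifier.

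Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total 15), libraries were scaled by TMM, and a quasi-likelihood F-test with robust estimation compared SphK1 with vector without a replicate block. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, and a gene was called at an adjusted p under 0.05. Levels are CPM, TMM-scaled counts as a share of the library, as mean ± SD of 2 libraries, and log2 fold changes are SphK1 minus vector with a standard error derived from the F statistic. On counts simulated from the libraries' own means (14231 genes), the test recovered 62% of genes changed 1.25-fold and 79.6% of those changed 1.5-fold. It recovered 81.6% of those changed 2-fold and 98.0% of those changed 4-fold. It called 10 of 14034 unchanged genes, which were 5.95% of all calls made there. Few genes were changed in the simulation, whereas 51.0% of tested genes were called in the data. The number of false calls therefore does not carry over to the data.

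Before the data were examined, 28 gene lists were fixed: sphingolipid metabolism, S1P receptors and transport, thyroid differentiation, MAPK/ERK output, mesenchymal, epithelial junction and keratin, matrix proteases and inhibitors, NF-kB and cytokine, interferon response, antigen presentation, cell cycle, p53 targets, hypoxia and glycolysis, cholesterol synthesis, ER stress and amino acid response, YAP/TAZ targets, TGF-beta targets, Wnt targets, STAT3 targets, apoptosis regulators, angiogenic factors and receptors, lysosome and autophagy, immune, endothelial and fibroblast markers, mitochondrially encoded genes, cytosolic ribosomal proteins and replication-dependent histones. The 27 lists with at least 5 tested members were compared with all other tested genes by camera in limma 3.58.1, on log2 CPM with a prior count of 2 and an inter-gene correlation preset at 0.01, with Benjamini-Hochberg adjustment over lists. The same test with an estimated correlation and fry, which asks only whether a list's genes moved on balance in a single direction, were run beside it. On simulated counts a list moved 1.3-fold was called and no other list was. The simulated genes were drawn independently of each other, so false list calls from correlated genes could not appear there.

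Named genes followed a rule fixed at the same time: SPHK1 and SPHK2, the 12 genes with the largest rise and the 12 with the largest fall among called genes with a mean of at least 5 CPM, an approved symbol and groups that did not overlap, up to 4 members of each list with the smallest p, and 11 genes named in advance (FN1, VIM, CDH1, CDH2, MMP2, MMP9, S1PR1, S1PR2, S1PR3, PAX8 and NKX2-1). Members that moved against the rest of a list, and a few further members given as examples, were chosen after their values were seen. Reads of genes that overlap on opposite strands are not separable with this kit, nor are those of near-identical copies such as HLA-B and HLA-C, and this is noted where the overlapping gene or copy held more than 10% of the gene's count.

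The alternatives fixed in advance were other scalings, DESeq2 1.42.0, limma-voom, other filters on low counts, protein-coding genes alone, removal of SPHK1 before scaling, estimation without robustness, the replicate number as a block, each library left out in turn, and other settings of the set test. Corrections for GC content and transcript length, removal of mitochondrial genes or of genes seen mainly in vector replicate 2, and a test against a minimum fold of 1.2 were added after the data were seen. Among named genes, the minimum-fold test was examined for SPHK1 alone. Ranges over the alternatives given for other single genes leave it out. GC content and length came from the longest GENCODE 29 transcript of each gene and were available for 99.5% of tested genes. Tables and figures were made in Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9.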

Results

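Gene expression was measured by RNA-seq in TPC1 papillary thyroid cancer cells with stable overexpression of SphK1 and in TPC1 cells with the empty vector, with 2 libraries per group. The vector libraries held 18781451 and 18426010 counts and the SphK1 libraries 18855153 and 19001383. At least 1 read was counted for 30145 genes. Log2 CPM correlated across genes at r = 0.997 between the vector libraries and 0.998 between the SphK1 libraries, against 0.978 to 0.979 between groups. Replicates differed by more than sampling noise, with a chi-square per degree of freedom of 1.63 for vector and 1.43 for SphK1, and were counted as 2 samples each. The first principal component separated the groups and held 79.5% of the variance. The next, with 10.6%, mainly separated the vector libraries from each other.

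The comparison asked which genes change when SphK1 is overexpressed. SPHK1 mRNA was 22-fold higher in the SphK1 libraries. Fibronectin (FN1, 3.34-fold) rose, as did 20 of 27 matrix proteases and inhibitors, among them cathepsin B (CTSB, 5.24-fold), urokinase (PLAU, 3.98-fold) and the collagenase MMP1, which went from 0.35 ± 0.12 to 10.1 ± 0.77 CPM (SD, n = 2). Of 26 p53 targets 22 rose, including the cell cycle inhibitor CDKN1A (log2 fold change 1.71 ± 0.03, SE), while 32 of 38 cell cycle genes fell, including cyclin B1 (CCNB1, -1.37 ± 0.03). Interferon-response (15 of 28), hypoxia (23 of 33), cholesterol synthesis (18 of 25), MAPK-output (18 of 27) and lysosomal (20 of 28) genes rose more often than they fell, and 17 of 21 targets of the Hippo-pathway coactivators YAP and TAZ fell. The camera calls of all these lists were lost with an estimated inter-gene correlation (camera adjusted p from 0.208 to 0.469, Benjamini-Hochberg). Among S1P receptor genes S1PR3 rose, and S1PR1 and S1PR2 did not pass the test.

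SPHK1 (ENSG00000176170, a protein-coding gene on chromosome 17 from 76376584 to 76387860, plus strand, GRCh38) had 457 and 477 counts in the vector libraries and 10584 and 10555 in the SphK1 libraries. Its level rose from 25.2 ± 1.12 to 558 ± 2.52 CPM (SD, n = 2), a log2 fold change of 4.47 ± 0.04 (SE; edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 3.29e-78). Reads of the gene body and of an introduced copy were not distinguished, and the gene overlaps PRPSAP1 on the opposite strand. Summed over all libraries, PRPSAP1 had 3161 counts, 14.3% of the SPHK1 sum, most of which lies in the SphK1 libraries. Its share against SPHK1 in the vector libraries alone was not computed, so the vector level of SPHK1 is less certain. SPHK1 was high in both SphK1 libraries, including replicate 2, whose description names Sphk2. SPHK2 (ENSG00000063176, chromosome 19 from 48619291 to 48630717, plus strand) was at 29.8 ± 1.10 CPM in vector and 25.4 ± 1.32 in SphK1 libraries (log2 fold change -0.23 ± 0.07, edgeR adjusted p = 0.0033). That call was lost with DESeq2 (adjusted p = 0.0638) and with edgeR without vector replicate 1 (0.0653) or without SphK1 replicate 1 (0.0771). Over all alternatives the adjusted p for SPHK2 ranged from 0.00193 to 0.0771. SPHK2 overlaps the far more abundant RPL18 on the opposite strand, and also DBP, whose count is 13.3% of that of SPHK2.

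Of 14485 genes tested, 7391 (51.0%) were called by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 3726 higher and 3665 lower in SphK1. Most changes were small: 73.8% of called genes differed by less than 1.5-fold, and 867 differed by at least 2-fold, 551 higher and 316 lower. An unadjusted edgeR p under 0.05 was found for 8043 genes. The groups did not overlap for 73.6% of tested genes, where chance gives 33.3% for 2 libraries against 2. A test against a minimum fold of 1.2, added after the data were seen, called 2827 genes, 1588 higher and 1239 lower. With a stricter filter on low counts, 325 genes were called at 2-fold or more, since low-count genes leave the test.

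**Figure D1:**
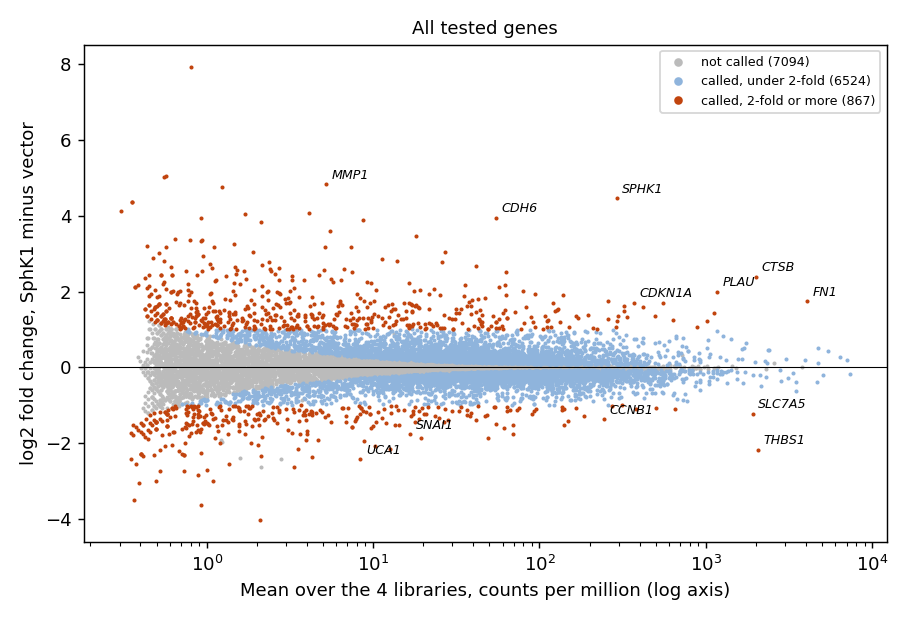
Mean level over the 4 libraries in CPM (log axis) against the fitted log2 fold change, SphK1 minus vector, for each of the 14485 tested genes, coloured by the edgeR call. The 867 genes called at 2-fold or more lie at low and high levels, and 325 were called so with the stricter filter on low counts. SPHK1, CTSB, PLAU, FN1 and THBS1 are among the abundant ones.

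The largest rises among genes of at least 5 CPM, besides SPHK1, were in MMP1 (log2 fold change 4.83 ± 0.25, SE), the kidney cadherin CDH6 (3.94 ± 0.07; 6.66 ± 0.095 to 103 ± 2.99 CPM, SD, n = 2), the interferon-induced OASL (3.88 ± 0.17), the endothelial receptor tyrosine kinase TIE1 (3.59 ± 0.21) and thrombomodulin (THBD, 3.46 ± 0.11). ABTB3, PTPN22, SLFN5, MEGF11, XDH, SPOCD1 and the metalloprotease ADAM12 followed, with log2 fold changes from 3.18 down to 2.69. The largest falls were in the long noncoding RNA UCA1 (-2.42 ± 0.14), thrombospondin 1 (THBS1, -2.17 ± 0.03; 3353 ± 18.6 to 745 ± 2.06 CPM, SD, n = 2), the PDGF receptor PDGFRB (-2.16 ± 0.11), HOGA1 (-2.08 ± 0.13) and ZBED2 (-1.95 ± 0.13). TGFB2 (-1.87 ± 0.06), which encodes a TGF-beta ligand, PLAC8, SAPCD2, the transcriptional repressor SNAI1 (-1.77 ± 0.09), the HLH inhibitor ID3 (-1.60 ± 0.05), DCLK1 and NEURL1B made up the rest. All of these 24 genes were called by edgeR, with adjusted p from 5.87e-58 for CDH6 and 4.92e-70 for THBS1 to 1.38e-16 for NEURL1B (Benjamini-Hochberg).

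**Figure D2:**
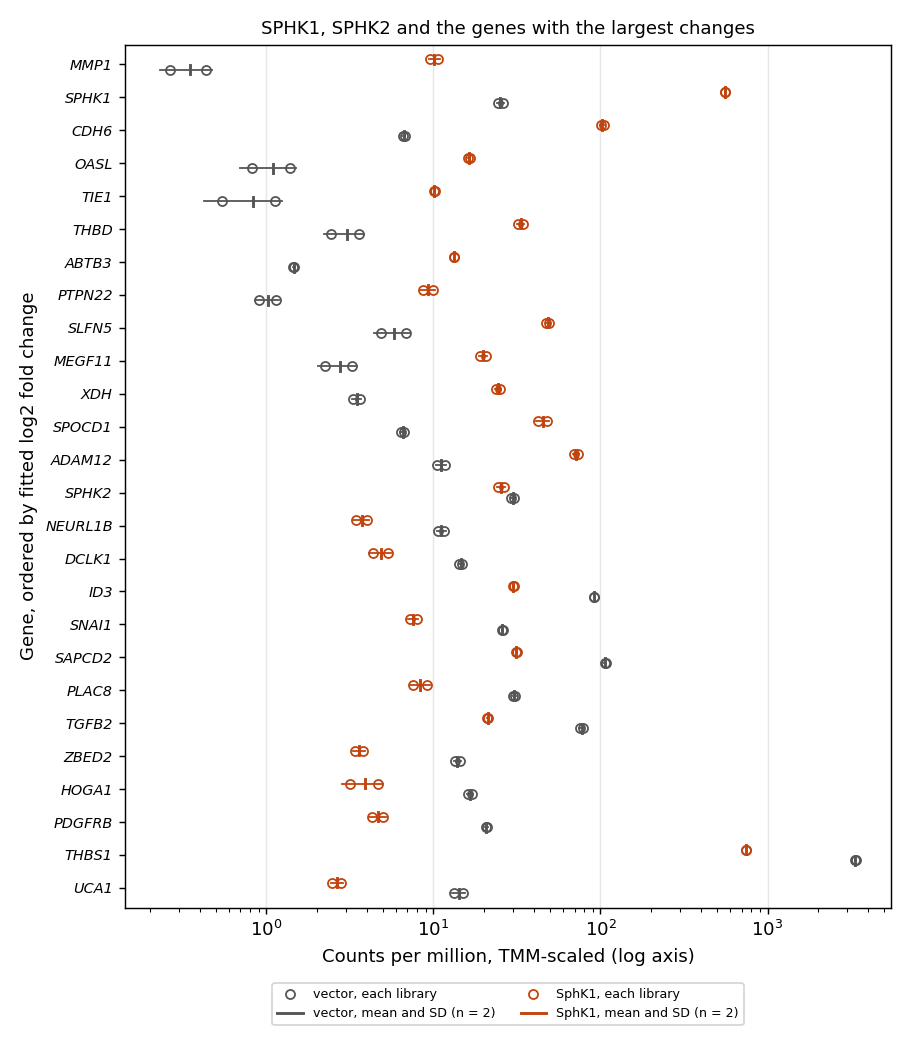
TMM-scaled CPM (log axis) in each library (circles), with group means (vertical ticks) and SD (horizontal bars, n = 2), for SPHK1, SPHK2 and the 12 genes with the largest rise and the 12 with the largest fall. The genes with the largest changes were chosen among genes whose groups do not overlap. The groups do not overlap for SPHK1 and SPHK2 either, and SPHK2 has the smallest gap (29.8 against 25.4 CPM).

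Across the 27 lists tested, 11 passed camera with Benjamini-Hochberg adjustment, 9 upward and 2 downward. None of them passed with an estimated inter-gene correlation (0 of 27 lists by camera, against 22 by fry), and those p-values are given with each list. The estimate was at or below the preset 0.01 for cell cycle (0.0085), matrix proteases (0.0020), hypoxia (-0.0012), cholesterol synthesis (-0.0073), interferon response (-0.026) and YAP/TAZ targets (-0.047). A high correlation among members therefore does not account for those losses. That setting also takes its degrees of freedom from the few libraries rather than from the genes. For the other lists that passed, the estimate was above the preset. Counts of members that rose or fell use the adjustment over all genes, with the count adjusted over the list alone beside it.

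Matrix proteases and their inhibitors showed the largest shift of a tested list. Of 27 tested members 20 rose and 3 fell (20 and 3 adjusted over the list alone), with a median log2 fold change of 0.80 (camera adjusted p = 1.78e-05 with Benjamini-Hochberg adjustment; adjusted p = 0.208 with an estimated correlation). CTSB (ENSG00000164733, chromosome 8 from 11842524 to 11869448, minus strand) rose from 646 ± 1.54 to 3383 ± 24.6 CPM (SD, n = 2), and PLAU (ENSG00000122861, chromosome 10 from 73909177 to 73917497, plus strand) from 469 ± 11.5 to 1866 ± 4.77 CPM. The membrane collagenase MMP14 rose by a log2 fold change of 1.26 ± 0.03 (SE), the gelatinase MMP9 by 4.07 ± 0.25, from 0.46 to 7.79 CPM, and the gelatinase MMP2 by 0.37 ± 0.05. Inhibitors were among the members that rose, namely the metalloprotease inhibitor TIMP1 (1.49 ± 0.03) and the serine protease inhibitor SERPINE2 (1.18 ± 0.04), while TIMP2 (-0.35), ADAM10 (-0.35) and CTSD (-0.14) fell.

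Mesenchymal genes moved both ways. FN1 (ENSG00000115414, chromosome 2 from 215360440 to 215436172, minus strand) rose from 1868 ± 19.7 to 6245 ± 55.4 CPM (SD, n = 2), and the matrix genes TNC (log2 fold change 1.76 ± 0.03, SE) and TGFBI (2.02 ± 0.05) rose too. THBS1 and SNAI1 fell, and the intermediate filament gene VIM fell slightly (-0.12 ± 0.03). Unlike SNAI1, the transcription factor genes SNAI2 (0.78 ± 0.07), ZEB1 (0.57 ± 0.05) and ZEB2 (0.56 ± 0.08) rose, and TWIST1 and TWIST2 were not called. In all, 12 of 27 members rose and 8 fell (12 and 8 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.205, Benjamini-Hochberg). N-cadherin (CDH2) was at 50.5 ± 0.76 and 45.7 ± 4.10 CPM (edgeR adjusted p = 0.0235), a call lost without vector replicate 1 (0.147), without SphK1 replicate 1 (0.570) and with DESeq2 (0.161), in a range of 0.00207 to 0.570 over all alternatives. Of 16 epithelial junction and keratin genes 8 rose and 5 fell (8 and 5 adjusted over the list alone; camera adjusted p = 0.611, Benjamini-Hochberg). The tight junction gene CLDN1 rose (0.42 ± 0.03) and the plakophilin PKP3 fell (-0.76 ± 0.06). E-cadherin (CDH1) had too few reads to test, with 5 and 2 counts in the vector and 1 and 2 in the SphK1 libraries.

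Cell cycle genes fell as a list, with 32 of 38 lower and 4 higher (33 and 4 adjusted over the list alone) and a median log2 fold change of -0.45 (camera adjusted p = 1.47e-09, Benjamini-Hochberg; adjusted p = 0.208 with an estimated correlation). CCNB1 (ENSG00000134057, chromosome 5 from 69167010 to 69178245, plus strand) fell from 354 ± 0.17 to 137 ± 0.31 CPM (SD, n = 2), the anaphase activator CDC20 by a log2 fold change of -1.01 ± 0.03 (SE) and the mitotic kinase PLK1 by -0.99 ± 0.03. KIF20A (-1.53 ± 0.04), a mitotic kinesin, overlaps BRD8 and CDC23 on the opposite strand. The members that rose were CDK1 (0.19), PCNA (0.17), CDC45 (0.26) and CCNE2 (0.25), of which PCNA and CDC45 act in DNA replication. Among p53 targets 22 of 26 rose and 1 fell (22 and 1 adjusted over the list alone), with a median of 0.53 (camera adjusted p = 1.76e-07, Benjamini-Hochberg; adjusted p = 0.277 with an estimated correlation). CDKN1A (ENSG00000124762, chromosome 6 from 36676460 to 36687339, plus strand) went from 173 ± 6.26 to 564 ± 8.92 CPM, the stress cytokine GDF15 rose by 2.16 ± 0.05 and TP53INP1 by 1.55 ± 0.07, and PLK2 fell (-0.68 ± 0.03). Apoptosis regulators did not pass as a list, with 12 of 25 higher and 7 lower (12 and 7 adjusted over the list alone; camera adjusted p = 0.205, Benjamini-Hochberg). The proapoptotic PMAIP1 (0.96 ± 0.05) and the antiapoptotic MCL1 (0.35 ± 0.03) rose, and the antiapoptotic BCL2L1 (-0.59 ± 0.03) and BIRC5 (-0.81 ± 0.03) fell.

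Hypoxia and glycolysis genes rose, 23 of 33 higher and 3 lower (23 and 3 adjusted over the list alone; median 0.34, camera adjusted p = 1.78e-05, Benjamini-Hochberg; adjusted p = 0.208 with an estimated correlation). ANGPTL4 rose by a log2 fold change of 1.54 ± 0.04 (SE), the endothelial growth factor VEGFA by 1.22 ± 0.04, NDRG1 by 0.74 ± 0.03 and the glycolytic enzyme PGK1 by 0.65 ± 0.03. The glucose transporter SLC2A1 (-0.49), the glycolytic regulator PFKFB3 (-0.60) and the aldolase ALDOC (-1.51) fell. Angiogenic factors and their receptors had 10 of 18 members higher and 4 lower (10 and 4 adjusted over the list alone) and did not pass (camera adjusted p = 0.205, Benjamini-Hochberg). The VEGF coreceptors NRP1 (0.93 ± 0.03) and NRP2 (0.95 ± 0.03) and the growth factor FGF5 (1.61 ± 0.06) rose. The growth factors PDGFB (-2.73 ± 0.50) and PGF (-0.77 ± 0.08) and the angiopoietin receptor TEK (-2.70 ± 0.43) fell.

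MAPK/ERK output genes rose, 18 of 27 higher and 4 lower (19 and 4 adjusted over the list alone; median 0.50, camera adjusted p = 0.000456, Benjamini-Hochberg; adjusted p = 0.469 with an estimated correlation). The members that rose included feedback inhibitors of the pathway, the phosphatase DUSP5 (log2 fold change 0.78 ± 0.04, SE) and SPRED3 (1.65 ± 0.09), as well as PHLDA1 (1.28 ± 0.03). Cyclin D1 (CCND1, -0.38 ± 0.03), MYC (-0.10), EPHA2 (-0.21) and EPHA4 (-1.04) fell. The NF-kB and cytokine list had 12 of 26 members higher and 6 lower (14 and 6 adjusted over the list alone) and did not pass (camera adjusted p = 0.105, Benjamini-Hochberg), although it passed without vector replicate 1 (0.0191) or vector replicate 2 (0.0164), in a range of 0.0164 to 0.469 over the camera alternatives. TNFAIP2 (-0.77 ± 0.03) and the NF-kB inhibitor NFKBIA (-0.61 ± 0.06) fell, and SOD2 (0.70 ± 0.03), which overlaps WTAP on the opposite strand, rose. STAT3 targets had 9 of 17 members higher and 5 lower (9 and 5 adjusted over the list alone; camera adjusted p = 0.546, Benjamini-Hochberg). The cytokine-signalling inhibitor SOCS1 rose from 1.84 ± 0.71 to 9.3 ± 0.099 CPM (SD, n = 2), and the kinase PIM1 fell (-1.15 ± 0.18).

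Interferon-response genes rose, 15 of 28 higher and 2 lower (17 and 2 adjusted over the list alone; median 0.45, camera adjusted p = 0.00014, Benjamini-Hochberg; adjusted p = 0.208 with an estimated correlation). OASL went from 1.10 ± 0.40 to 16.3 ± 0.22 CPM (SD, n = 2), IFIT3 from 17 ± 0.63 to 46.2 ± 2.81 and IFIT1 from 12.3 ± 0.36 to 24.6 ± 0.24, and IFIT2 (log2 fold change 1.71 ± 0.10, SE) is uncertain because it overlaps LIPA on the opposite strand. OAS3 (-0.32) and the immunoproteasome subunit PSMB9 (-0.60) fell. Of 18 antigen presentation genes 11 rose and PSMB9 fell (11 and 1 adjusted over the list alone; median 0.19, camera adjusted p = 0.0196, Benjamini-Hochberg; adjusted p = 0.588 with an estimated correlation). That call was lost without vector replicate 1 (camera adjusted p = 0.0516, Benjamini-Hochberg), in a range of 0.0126 to 0.588 over the camera alternatives. Examples were B2M (0.34 ± 0.03), the light chain of class I molecules, and HLA-B (0.70 ± 0.05), whose reads may be shared with HLA-C.

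Targets of YAP and TAZ fell, 17 of 21 lower and 3 higher (17 and 3 adjusted over the list alone; median -0.49, camera adjusted p = 0.000135, Benjamini-Hochberg; adjusted p = 0.208 with an estimated correlation). CCN2 went from 215 ± 6.45 to 81.2 ± 3.64 CPM (SD, n = 2) and the receptor tyrosine kinase AXL from 998 ± 15 to 543 ± 2.23 CPM, while the ectonucleotidase NT5E (log2 fold change 0.98 ± 0.03, SE), AMOTL1 (0.80) and IGFBP3 (0.14) rose. TGF-beta targets split, with 10 of 23 higher and 11 lower (10 and 11 adjusted over the list alone; camera adjusted p = 0.858, Benjamini-Hochberg). The list's mean was above 0 (0.05), while its median (-0.07) and the direction of its test were downward. TGFBI and PMEPA1 (1.43 ± 0.05) rose, and TGFB2 and ID3 fell. Wnt targets had 6 of 14 members higher and 5 lower (6 and 5 adjusted over the list alone; camera adjusted p = 0.602, Benjamini-Hochberg). The R-spondin receptors LGR5 (1.89 ± 0.07) and LGR4 (0.57 ± 0.04) and the hyaluronan receptor CD44 (0.83 ± 0.02) rose, while the receptor TNFRSF19 (-2.16 ± 0.21) and the Wnt inhibitor DKK1 (-1.08 ± 0.13) fell.

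Sphingolipid metabolism genes, the enzymes around SphK1, moved evenly, with 13 of 39 higher and 12 lower (13 and 12 adjusted over the list alone; camera adjusted p = 0.858, Benjamini-Hochberg). The median (-0.00239) was below 0, and the mean (0.0146) and the direction of the test were above it. The saposin precursor PSAP (log2 fold change 0.44 ± 0.03, SE) rose, and SPTLC2 (-0.65 ± 0.04), a subunit of the enzyme that starts sphingolipid synthesis, ALDH3A2 (-0.76 ± 0.05) and the glucosylceramide synthase UGCG (-0.44 ± 0.03) fell. Of 14 genes of S1P receptors and transport 4 rose and 2 fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.858, Benjamini-Hochberg). The exporter ABCC1 (-0.53 ± 0.04) and the S1P-binding PHB2 (-0.27 ± 0.03) fell, and the lipid transporters MFSD2A (0.61 ± 0.11) and ABCA1 (0.26 ± 0.05) rose. S1PR3 rose from 12 ± 1.43 to 16.2 ± 0.33 CPM (SD, n = 2). S1PR1 was at 2.21 ± 0.20 and 3.04 ± 0.34 CPM (edgeR adjusted p = 0.0763, Benjamini-Hochberg) and S1PR2, which overlaps the abundant DNMT1, at 2.37 ± 0.35 and 2.67 ± 0.49 CPM (edgeR adjusted p = 0.564).

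Cholesterol synthesis genes rose, 18 of 25 higher and 2 lower (19 and 2 adjusted over the list alone; median 0.38, camera adjusted p = 0.000212, Benjamini-Hochberg; adjusted p = 0.208 with an estimated correlation). INSIG1, a sterol sensor, rose by a log2 fold change of 1.35 ± 0.05 (SE), the sterol carrier STARD4 by 0.96 ± 0.06 and the transcription factor SREBF2 by 0.44 ± 0.03, whereas the enzymes EBP (-0.39) and ACAT2 (-0.29) fell. Lysosome and autophagy genes rose, 20 of 28 higher and 3 lower (23 and 3 adjusted over the list alone; median 0.22, camera adjusted p = 0.000216, Benjamini-Hochberg; adjusted p = 0.469 with an estimated correlation). Besides CTSB, the acid glucosidase GAA (0.89 ± 0.05) and the sialidase NEU1 (0.78 ± 0.06) rose, and the proton pump subunit ATP6V0D2 went from 0.19 ± 0.035 to 3.2 ± 0.25 CPM (SD, n = 2). CTSD (-0.14), GABARAPL1 (-0.59) and GLA (-0.23) fell. ER stress and amino acid response genes split, 15 of 31 higher and 13 lower (15 and 13 adjusted over the list alone; camera adjusted p = 0.981, Benjamini-Hochberg), with a median above 0 (0.06) but a mean (-0.03) and a direction of the test below it. The amino acid transporter SLC7A5 fell from 2682 ± 69.5 to 1144 ± 3.35 CPM, its partner SLC3A2 by -1.07 ± 0.03 and the serine synthesis enzymes PHGDH and PSAT1 by -1.10 ± 0.04 and -0.79 ± 0.03.

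Thyroid differentiation genes had 5 of 10 tested members higher and 2 lower (5 and 2 adjusted over the list alone) and did not pass as a list (camera adjusted p = 0.580, Benjamini-Hochberg). The thyroid transcription factor PAX8 rose from 403 ± 7.15 to 640 ± 3.17 CPM (SD, n = 2), while the thyroid hormone receptor THRB fell from 40.7 ± 0.17 to 15.5 ± 0.64 and GLIS3 from 65.4 ± 1.08 to 50 ± 2.11. The thyroid transcription factor NKX2-1 was not tested, with 0 counts in all 4 libraries.

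Mitochondrially encoded genes rose, 11 of 13 with 0 lower (12 and 0 adjusted over the list alone; median 0.20, camera adjusted p = 0.000456, Benjamini-Hochberg; adjusted p = 0.607 with an estimated correlation). They took 4.67% and 4.86% of counts in SphK1 against 3.91% and 3.83% in vector libraries. MT-CO3 (log2 fold change 0.52 ± 0.02, SE) and MT-ND2 (0.47 ± 0.03) are examples, and MT-CO3 shares a boundary with MT-ATP6. Cytosolic ribosomal protein genes had 1 of 30 higher and 15 lower (1 and 15 adjusted over the list alone), all small, such as RPL5 (-0.19 ± 0.03) and RPL3 (-0.17 ± 0.02), and did not pass (camera adjusted p = 0.0851, Benjamini-Hochberg). Replication-dependent histones had 3 of 7 higher and 1 lower (3 and 1 adjusted over the list alone; camera adjusted p = 0.205, Benjamini-Hochberg). H2BC12 (1.36 ± 0.19) and H1-2 (0.63 ± 0.10) rose and H3C10 (-0.91 ± 0.32) fell. The H3C10 call was lost with DESeq2 (adjusted p = 0.154) and with edgeR without vector replicate 1 (0.202) or SphK1 replicate 2 (0.212), in a range of 0.00951 to 0.212 over the 19 alternatives that tested it. The H4C8 call, among those higher, was lost without SphK1 replicate 2 (edgeR adjusted p = 0.0754), in a range of 0.000506 to 0.0754 over the 19 that tested it.

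Markers of other cell types were measured as well. Of 20 immune cell markers 4 could be tested, too few for the set test, and 3 rose (3 adjusted over the list alone). All 3 stayed low: the T cell receptor constant gene TRAC had 1 and 0 counts in vector and 23 and 18 in SphK1 libraries, and ITGAX and CSF1R were at 0.74 and 1.16 CPM in SphK1. The ITGAX call was lost without vector replicate 2 or SphK1 replicate 2 (edgeR adjusted p = 0.0717 and 0.0948; range over the 18 alternatives that tested it 0.000783 to 0.0948). The CSF1R call was lost without vector replicate 1 or SphK1 replicate 2 (edgeR adjusted p = 0.204 and 0.120) and with DESeq2 (0.117), in a range of 0.00325 to 0.204 over the 19 alternatives that tested it. Endothelial markers had 3 of 7 higher and 2 lower (3 and 2 adjusted over the list alone; camera adjusted p = 0.340, Benjamini-Hochberg). TIE1 rose from 0.83 ± 0.41 to 10.1 ± 0.026 CPM (SD, n = 2) and its relative TEK fell from 1.75 ± 0.55 to 0.26 ± 0.074. The calls of ROBO4 (higher) and EGFL7 (lower) were lost under some alternatives, with Benjamini-Hochberg adjusted p over all alternatives from 0.000433 to 0.0617 for ROBO4 and from 0.000996 to 0.286 for EGFL7. The ranges for ROBO4 and EGFL7 leave out the test against a minimum fold of 1.2. Fibroblast markers had 3 of 7 higher and 2 lower (3 and 2 adjusted over the list alone, camera adjusted p = 0.981, Benjamini-Hochberg). The matrix genes FBLN1 (log2 fold change 0.49 ± 0.04, SE) and COL6A3 (1.32 ± 0.18) rose and PDGFRB fell.

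**Figure D3:**
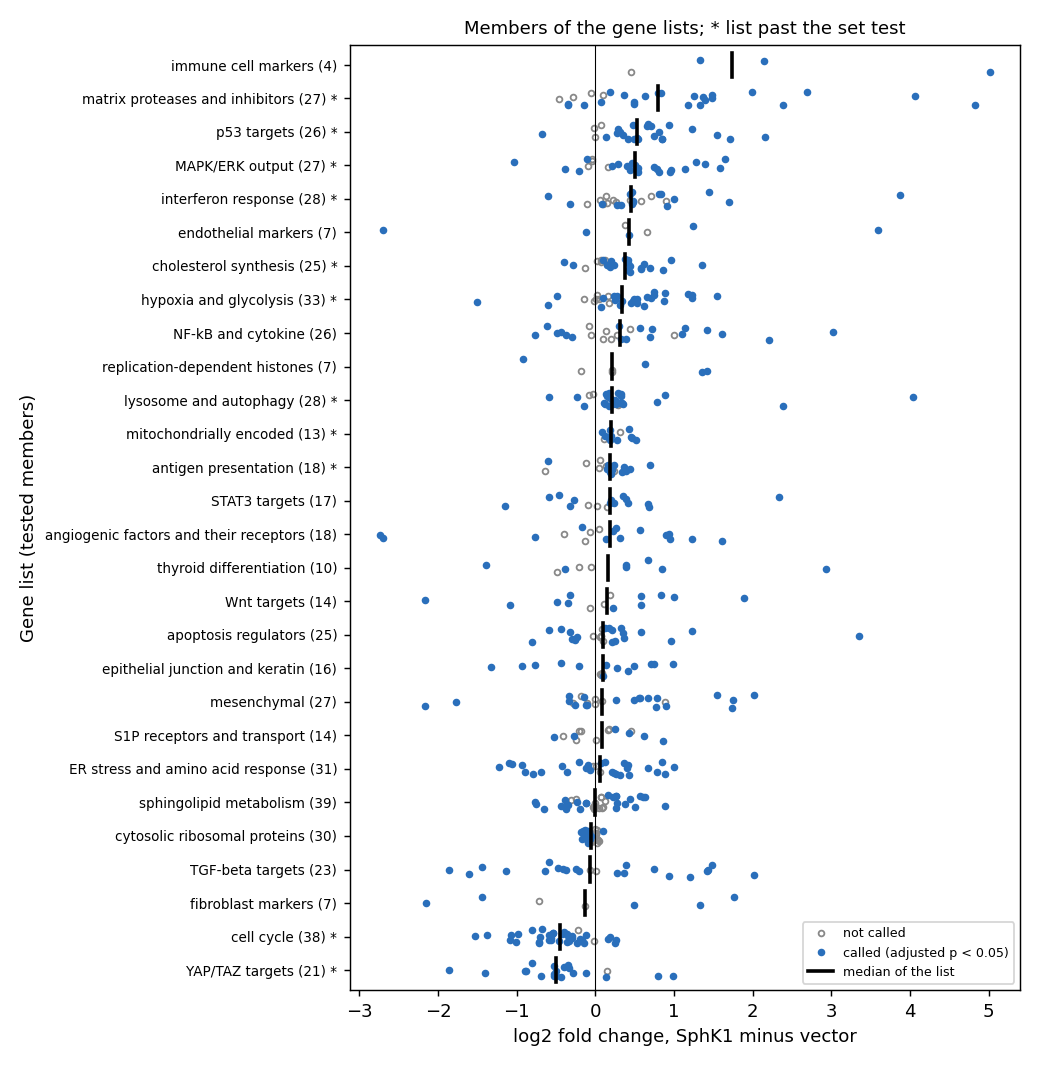
Fitted log2 fold change, SphK1 minus vector, of each tested member of the 28 gene lists (points, filled where called by edgeR), with the median of each list (black bar) and the number of tested members in brackets. Asterisks mark the 11 lists past camera at the preset inter-gene correlation, with medians from -0.49 for YAP/TAZ targets to 0.80 for matrix proteases and inhibitors. None of them passed with an estimated correlation.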

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

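The corrections for GC content and length, the removal of mitochondrial genes or of genes seen mainly in vector replicate 2, and the test against a minimum fold of 1.2 were chosen after the data were seen, and the other alternatives before. With a library left out, the remaining library of its group is assumed to vary like the other group. Without each library in turn, 6309 to 6463 genes were called, 3168 to 3271 higher and 3141 to 3223 lower, 814 to 866 at 2-fold or more, and the SPHK1 log2 fold change was 4.43 to 4.52. DESeq2 called 5200 genes, of which 5196 were also called by edgeR. The minimum fold of 1.2 left 2827 calls (1588 higher, 1239 lower), a higher share of 56.2% against 50.4%, and the stricter filter left 325 at 2-fold or more, because fewer genes enter the test. Lists past the set test numbered 11 to 12 without each library, 0 with an estimated correlation and 22 by fry, which does not compare a list with other genes. With the replicate number as a block (replicate block), 7568 genes and 11 lists were called, and the replicate differences of the 2 groups were close to uncorrelated across genes (r = -0.02 over 14485 genes, 0.09 over the 6298 highly expressed ones), which gives little sign that the numbers pair the samples. Of 2620 values for 132 named genes under 20 alternatives, 2598 kept their direction and call, 21 lost the call, and 1 reversed, S1PR2, at a log2 fold change of -0.029 without SphK1 replicate 1 and 0.35 without SphK1 replicate 2 and not called in either. This tally of named genes leaves out the minimum fold of 1.2, which left 2827 calls among all genes. It also skips a gene where an alternative did not test it or gave it no adjusted p. Of 297 list results, 262 were the same, 12 lost and 13 gained the call, and 10 changed direction, all in lists that did not pass. ER stress changed direction with the block (adjusted p = 0.923), on ranks (0.919) and without vector replicate 1 (0.904), vector replicate 2 (0.941) or SphK1 replicate 2 (0.962). Fibroblast markers did so on ranks (0.935) and without vector replicate 2 (0.786), TGF-beta targets without vector replicate 2 (0.941) or SphK1 replicate 1 (0.980), and sphingolipid metabolism without SphK1 replicate 1 (0.980), all by camera with Benjamini-Hochberg adjustment. Over all single libraries left out, with or without a change of direction, adjusted p was 0.904 to 0.980 for ER stress, 0.398 to 0.842 for fibroblast markers, 0.693 to 0.980 for TGF-beta targets and 0.690 to 0.980 for sphingolipid metabolism. The cause was not tested. The lost calls were in SPHK2, CDH2, CSF1R, ITGAX, EGFL7, ROBO4, H3C10 and H4C8.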

Other observations

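The tests in this part, namely those of GC and length trends, of the genes seen mainly in vector replicate 2 and of Gene Ontology terms, were chosen after the data were seen. Among 634 Gene Ontology processes of 15 to 200 tested genes, taken from the annotation in the deposited table, 16 passed camera with Benjamini-Hochberg adjustment, 4 upward and 12 downward, and 0 passed with an estimated correlation (lowest adjusted p = 0.866). As for the gene lists, that setting takes its degrees of freedom from the few libraries, so this loss alone does not decide whether a term moved. Among the 12 downward terms the largest median shifts were in protein breakdown through the anaphase-promoting complex (11 of 17 genes fell, 1 rose; median log2 fold change -0.36) and in mitotic sister chromatid segregation (13 of 20 fell, 3 rose; -0.25). Terms of RNA processing and translation moved less. Of 177 mRNA processing genes 89 fell and 18 rose (median log2 fold change -0.12, camera adjusted p = 0.00602, Benjamini-Hochberg). Of 92 genes of mitochondrial translation 44 fell and 2 rose (-0.11, 0.00602), although 11 of 13 mitochondrially encoded mRNAs rose. For translational initiation, 31 of 85 genes fell and 0 rose (-0.09, camera adjusted p = 0.0441, Benjamini-Hochberg). The 4 upward terms were cell adhesion (96 of 187 rose, 34 fell), disassembly of the extracellular matrix (32 of 52 rose, 6 fell), collagen catabolism (19 of 30 rose, 5 fell) and RNA-mediated transposition (20 of 87 rose, 2 fell). Of all 14485 tested genes, 3726 rose and 3665 fell. The share of transposition genes that rose was below that of all tested genes, so that count alone shows no excess of risen genes.

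Outside the naming rule, 2 genes were picked after their values were seen. IL33, an alarmin cytokine on chromosome 9 from 6215786 to 6257983 (GRCh38), had 0 counts in both vector libraries and 23 and 38 in the SphK1 libraries, at least 20-fold higher against a floor of 3 counts over the vector group. The protocadherin-related gene FAT3 had 78 and 69 counts in vector and 6 and 3 in SphK1 libraries.

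About 51.0% of tested genes were called. Removing each library's trend with GC content left 7584 calls and removing the trend with transcript length left 7368, so neither trend alone accounts for the breadth. The chi-square per degree of freedom between libraries of different groups was at least 53.8, against 1.63 within vector. Each group appears to be a single stable line or batch as far as the labels tell, so an effect of SphK1 and a difference between lines, selections or culture batches cannot be told apart.

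Most cell cycle genes fell and most p53 targets rose, although both list calls were lost with an estimated correlation (camera adjusted p = 0.208 and 0.277, Benjamini-Hochberg). With GC and length trends both removed, the smaller of the ratios of the lists' medians to those without removal was 1.05, which argues against these trends. Culture density or growth phase at harvest could also lower cell cycle genes (median log2 fold change -0.45), and the labels give no density, so that it stays open beside an effect of SphK1, which was not tested separately.

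A set of 86 genes had reads mainly in vector replicate 2 (more than 4-fold over the other libraries and over the other vector library, binomial p under 1e-06), and the same rule found 0 genes in each other library, which argues against sampling noise. They held 2812 counts (0.0153% of the library), and 54 (62.8%) were processed pseudogenes, against 6.28% of 4776 genes with counts in the same range (Fisher's exact test, two-sided p = 3.59e-41) and 16.9% of the 178 of these nearest in counts elsewhere, whose counts there were still higher (median 18 against 2). The pseudogenes' median excess was 12.8-fold and that of their parent genes 1.03-fold over 43 pairs, a ratio of 12.4, but the pseudogenes were chosen for their excess and the parents are abundant, so this ratio does not exclude human RNA. The other 32 were protein-coding, including ACTG2 (0, 109, 0 and 3 counts in vector replicates 1 and 2 and SphK1 replicates 1 and 2), MYH11 (20, 114, 11 and 11) and COL3A1 (0, 43, 0 and 0). A smooth muscle list examined for these did not name their source. Its low-count members held few reads in vector replicate 2, such as CNN1 with 9. Abundant members such as FLNC (12500, 12947, 13255 and 13450 counts in the same order) differed little there, while ACTA2 had 117, 230, 335 and 322. A trace of reads from another organism may account for the pseudogenes (62.8%), but it and human RNA cannot be told apart for them, and a higher rate of misplaced reads was not tested.

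These 86 genes matter little for the edgeR calls, where 6 were tested and 0 called, but the authors' deposited table keeps them. There, 4110 genes had an adjusted p under 0.05, against 7391 called by edgeR here. Of the 4110, 601 changed at least 2-fold, 376 higher and 225 lower, and 41 of the 225 (18.2%) were among the 86. A further 2 genes with an adjusted p under 0.05 have a vector mean of 0 and no fold, and are not counted among the higher ones. Of these 225 lower genes, 20 have a fold of 0 in the authors' deposited table, and 18 of the 20 were among the 86.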
